A study of Mus musculus with 3 samples.

How the data were processed

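Total RNA of mouse embryonic stem cells with a conditional Pou5f1 knockout was profiled on Affymetrix arrays at 3 time points, day 0, day 1 and day 2, with 1 array per time point. Per the labels, RNA was extracted with Trizol, cleaned on RNeasy columns, amplified and labelled with biotin with a one-cycle labelling kit. The deposited values are array intensities, 1 per probe set, a set of short probes designed for the same transcript. Per the submitters' processing notes, MAS5 was used, and its version is not given in the sources used here. From the values themselves, the intensities deposited by the authors are linear, with no negative values, and share a 2% trimmed mean of 498 on each array once the control probe sets are left out. The day 2 column holds values for 45101 probe sets and the others for 45037, the difference being 64 control probe sets that were left out here. The day 2 column is also written in another number format. Whether that array was exported or processed apart from the others is not given in the sources used here, so a difference in processing is not excluded from any day 2 comparison beyond the shared trimmed mean. No present or absent call for single probe sets was used here, so the signal itself is the guide to what lies near background.

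Each array was scaled to a common 2% trimmed mean, which moved no array by a visible amount because the arrays already shared it. A constant of 55.9, the 40th percentile of all signals pooled over the arrays, was added before taking log2, and every difference and fold is on the log2(signal + constant) scale, which understates the change of dim genes. A probe set was kept when its mean signal over the 3 arrays reached the constant. This kept 26925 of 45037 probe sets, or 59.8%. Genes were named from the platform's annotation table. In it 34958 probe sets name 1 gene, 932 name several, and 9147 are not listed and stay unnamed. Of the probe sets with 1 gene, 34754 matched the gene table of mouse assembly GRCm38.p6 by Entrez identifier, and 0 symbols had to be changed. Probe sets naming several genes gave no gene a value. A gene is represented by its kept probe set with the highest mean signal, which left 12717 genes, 5906 of them with several kept probe sets.

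With 1 array per time point there is no replicate error and no test, and no p-value is given. Genes were counted by size, as at least 2-fold higher or lower, for day 2 against day 0, day 1 against day 0 and day 2 against day 1. The only error that the files allow is the spread between probe sets of the same gene, with a pooled SD of 0.34 in log2 for day 2 against day 0, 0.30 for day 1 against day 0 and 0.30 for day 2 against day 1. It covers probe error and leaves out the variation between cultures and between hybridisations. From the residuals of these probe sets, 100 sets of unchanged arrays sharing their day 0 array were simulated, to show how many genes pass the size rule with no change at all. The number of arrays limits the precision of every value.

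There were 29 gene lists, written before the data were examined: pluripotency, trophectoderm, primitive endoderm, primitive streak and mesoderm, neuroectoderm and epiblast, Hox genes, other developmental transcription factors, Polycomb repressive complexes 1 and 2, DNA methylation, cell cycle, cyclin-dependent kinase inhibitors with D cyclins, p53 targets, epithelial genes, mesenchymal genes, fibroblast and feeder markers, targets or feedback genes of FGF, LIF, BMP, Nodal and Wnt signalling, imprinted genes, stages and states outside these cells (2-cell stage and germ cell genes), stress response, glycolysis, sterol synthesis, ribosomal proteins and reference genes. For each list the median difference is given with an exact binomial 95% interval over its members, except for the 2-cell stage list, whose 5 measured members are too few for one. Its percentile among 10000 random lists of the same size, matched on mean signal in 20 bins, describes these arrays and is not a test. List symbols that were not found were looked up among older symbols. An error in this step was corrected after values had been seen: H19 and Duox2, which are current symbols without a probe set of their own, had been replaced by Nckap1 and Duox1, other genes that carry these names as synonyms. The correction removed these genes from the trophectoderm and imprinted lists and left the numbers of members past 2-fold as they were. Lists share members, so their results are not independent. Genes not measured are those without a probe set of their own or with a mean signal below the constant, and they are not analysed here.

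The same rule chose the genes that are named: Pou5f1; the 10 highest and 10 lowest genes for day 2 against day 0 and for day 1 against day 0; the 5 highest and 5 lowest for day 2 against day 1; and up to 4 members of each list with the largest difference at day 2, with further members past 2-fold where a list is described member by member. Clone names without a gene name, genes whose other kept probe sets went the other way, and genes represented by a probe set ending in _x_at were passed over in the rankings. Nanog, Sox2 and the other pluripotency genes past 2-fold come under the last part. The members Cdh1, Dnmt1, Dnmt3b, Eomes, Ezh2, Ring1, Rnf2, Slc2a3 and Vim, which were within 2-fold at day 2, and the genes of the day 1 peaks and troughs, were chosen after their values were seen.

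The alternatives, also fixed before the data were examined, were the values as deposited, equal array medians, quantile normalisation, equal medians of ribosomal protein genes, constants of 27.9 and 112, a floor at the constant in place of adding it, no filter on dim probe sets, a filter at the 60th percentile, the mean over a gene's probe sets, leaving out probe sets ending in _x_at, _s_at or _a_at, a 3-fold threshold, and random lists without matching. The counting and list steps were tested on simulated data for 12717 genes. For day 2 against day 0, all 50 genes simulated with a 3-fold change and all 50 with a 4-fold change passed the 2-fold rule, against 44% of those with a 2-fold change, 16% with a 1.5-fold change and 1.46% of unchanged genes. For day 1 against day 0, 56% of genes simulated with a 2-fold change and 0.791% of unchanged genes passed. The simulated changes were added on the log2(signal + constant) scale, so the constant did not compress them. A dim gene with the same fold in signal would pass less often. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.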

Results

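Gene expression was measured in mouse embryonic stem (ES) cells, which come from the early embryo, renew themselves in culture and can form all tissues of the body. The cells carried a conditional knockout of Pou5f1, the gene of Oct3/4, a POU-domain transcription factor needed for the pluripotent state. A conditional allele was used because ES cells that lack the gene permanently cannot be kept in culture. The question was which genes change their expression once Oct3/4 is gone. Total RNA was profiled at day 0, day 1 and day 2 of the knockout, with 1 array for each day and therefore no replicates, and all differences describe these 3 arrays. How the knockout was induced is not given in the sources used here. No culture without the knockout was profiled at day 1 or day 2. An effect of losing Oct3/4 therefore cannot be told apart from one of time in culture or of any inducing treatment. The median signal was 83.5 at day 0, 92.5 at day 1 and 87.6 at day 2. Across all probe sets, which are not independent replicates, the log2 signals correlated with r = 0.974 between day 1 and day 0, 0.974 between day 2 and day 1, and 0.959 between day 2 and day 0. The highest signals were 44382, 52453 and 53589, in the order of the days.

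The targeted gene was examined first. Pou5f1, which a single probe set measures, had a signal of 2400 at day 0, 40.8 at day 1 and 15.5 at day 2. On the log2 scale it was lower by −4.67 at day 1 and −5.10 at day 2, which are 25.4-fold and 34.4-fold after the constant was added. At day 1 Pou5f1 was already below the added constant of 55.9, and at day 2 only 18.3% of the probe sets on the array were dimmer. Which part of the gene was deleted is not given in the sources used here, so whether the probe set lies within it is unknown. Wherever it lies, its fall after day 0 goes with the day labels. The order of day 1 and day 2, both below the constant, is unresolved.

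**Figure D1:**
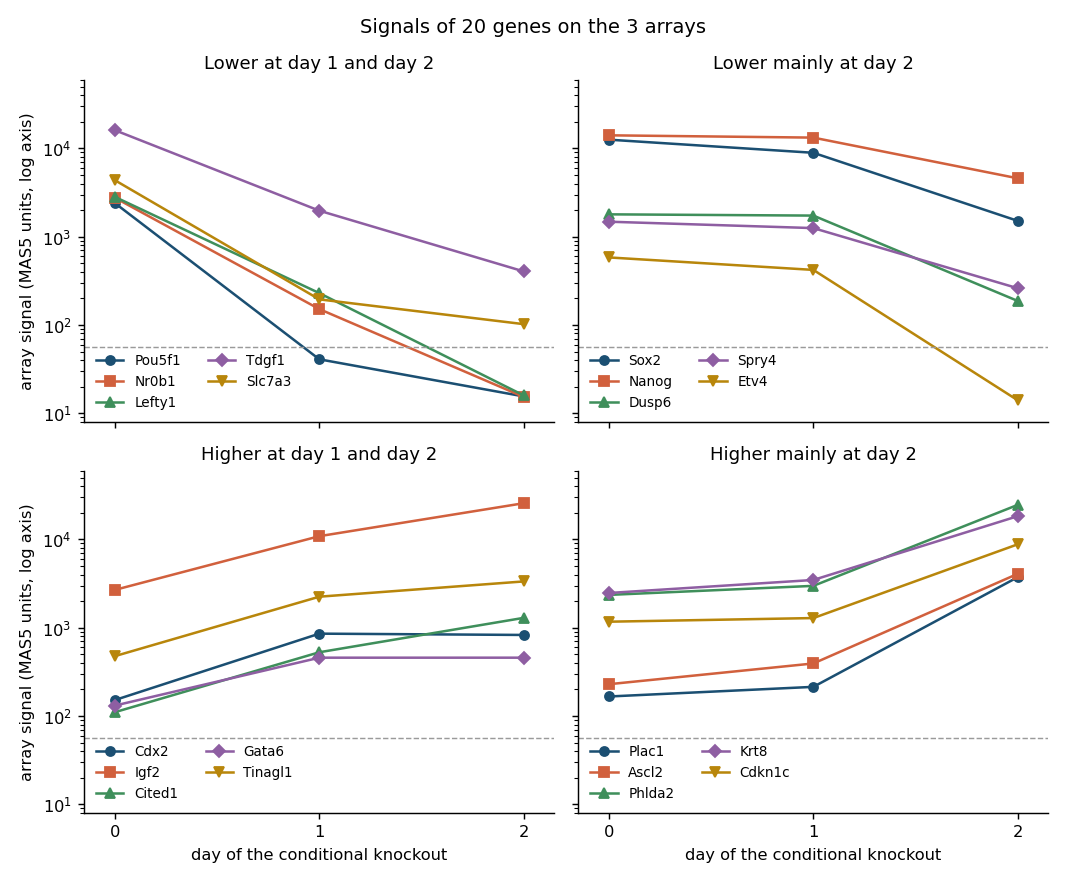
Signals of 20 genes at day 0, day 1 and day 2, with 1 array per day. The vertical axis is the array signal in MAS5 units on a log axis, the dashed line marks the added constant of 55.9, and each line is 1 gene. Pou5f1 went from 2400 to 15.5, Dusp6 was still at 1734 at day 1 and at 187 at day 2, and Plac1 went from 166 to 3740.

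At day 2 the genes furthest below day 0 were mostly genes of the pluripotency list, and 4 of the 10 named genes furthest above it were in the trophectoderm list. Lefty1, an inhibitor of Nodal signalling, was lower by −5.32 (signal 2821 to 15.9), Nr0b1, a nuclear receptor of ES cells, by −5.31 (2759 to 15.3), and Tdgf1, the Nodal co-receptor, by −5.13 (16080 to 404). Trh (−5.03), the precursor of thyrotropin-releasing hormone, Morc1 (−4.86), the amino acid transporter gene Slc7a3 (−4.81), Stmn2 (−4.69), the growth factor gene Fgf4 (−4.68) and Mymx (−4.40) completed the lowest 10 with Pou5f1. The day 2 signals of Lefty1, Nr0b1, Pou5f1 and Trh lay below the constant, which limits their differences and leaves their order unresolved. Plac1, a gene of the placenta, was higher by 4.10 (166 to 3740), and Ascl2, a transcription factor of trophoblast, by 3.86 (229 to 4081). They were followed by Vav3 (3.48), the imprinted genes Phlda2 (3.36, signal 2354 to 24651) and Igf2 (3.24, signal 2682 to 25737), Nxf7 (3.19), Ldoc1 (3.15), Mbnl3 (3.14), Nrk (3.11) and Cited1 (3.02). The day 0 signals of Vav3 (17.3) and Nxf7 (25.4) lay below the constant, so their place in the order is unresolved too. Another kept probe set gave 1.75 for Mbnl3, and another gave −2.42 for Fgf4. In all, 668 genes (5.25% of 12717) were at least 2-fold higher and 718 (5.65%) at least 2-fold lower. In simulated unchanged arrays the same rule gave on average 94.0 higher and 93.5 lower genes. When the arrays were scaled to equal medians of ribosomal protein genes, which moved the median of all genes by −0.13, the split was 520 higher and 876 lower.

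Pluripotency genes were lower almost throughout. Of 43 measured members, 36 were at least 2-fold lower at day 2, 0 were at least 2-fold higher and 7 stayed within 2-fold. Sox2, the partner of Oct3/4, was lower by −3.01 (signal 12563 to 1510), and Nanog by −1.61 (14073 to 4585). The naive-state factors Esrrb (−3.44), Klf2 (−3.09), Prdm14 (−2.84) and Klf4 (−1.93) were lower, as were Zfp42 (−2.62), Utf1 (−2.13) and Dppa5a (−1.58). The median of the list was −2.13 (95% interval −3.01 to −1.75), below all 10000 random lists of matched signal. The highest member was the glucose transporter gene Slc2a3 at 0.66, the only 1 of the 43 above 0. Pou5f1 itself is a member of this list.

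Genes of trophectoderm, the lineage of the early embryo that forms the placenta, were mostly higher. Of 34 measured members 24 were at least 2-fold higher and 2 at least 2-fold lower, and the median was 1.59 (95% interval 1.05 to 2.43), above all random lists. Besides Plac1 and Ascl2, the trophectoderm transcription factors Gata3 (2.56, signal 54.7 to 594) and Cdx2 (2.09, signal 152 to 828) were higher, along with Esx1 (2.44), Dlx3 (2.08), Gata2 (1.60), Hand1 (1.26) and Tfap2c (1.21). The members at least 2-fold lower were Esrrb (−3.44), which is also in the pluripotency list, and Bmp4 (−3.25, signal 4526 to 427). Eomes, another transcription factor of this lineage, was at −0.32. Elf5, Tpbpa, Ctsq and Psg17 had mean signals below the constant and were not analysed here.

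Keratin and claudin genes were higher, several of them also members of the trophectoderm list. Krt8 was higher by 2.86 (signal 2474 to 18358), Krt18 by 2.60 (4026 to 24610) and Krt19 by 2.38, and the claudin genes Cldn3 by 1.93 and Cldn7 by 1.55. Of 24 measured epithelial genes 11 were at least 2-fold higher, 6 of which are shared with the trophectoderm list, and 2, Jup (−1.50) and Esrp1 (−1.08), at least 2-fold lower. The value for Esrp1 was −0.999 with a constant of 112. The median was 0.81 (95% interval −0.08 to 1.55), above all random lists, and Cdh1, the gene of E-cadherin, was at 0.16. Among 16 mesenchymal genes 4 were at least 2-fold higher, the contractile or actin-binding genes Cald1 (2.08), Tpm1 (1.78), Tagln (1.60) and Acta2 (1.43). Fn1 (−1.28) and Mmp2 (−1.25) were lower, Mmp2 at only −0.10 when probe sets ending in _x_at, _s_at or _a_at were left out. The mesenchymal median was 0.32 (95% interval −0.39 to 1.43; percentile 98.3), or 0.83 with the filter at the 60th percentile, and Vim was at −0.71. Markers of fibroblasts, the usual feeder cells of ES cultures, were dim, with 11 of 19 below the constant, Col1a1 and Col3a1 among them. Of the 8 measured ones 0 were at least 2-fold higher and 1, Thy1 (−1.65), was lower, with a median of 0.27 (95% interval −1.65 to 0.62; percentile 83.2) that turned to −0.97 with the filter at the 60th percentile.

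Imprinted genes, which are expressed from the allele of a single parent and many of which act in placental growth, were higher as a group. Of 20 measured members 8 were at least 2-fold higher and 0 lower, and the median was 0.84 (95% interval 0.34 to 2.00), above all random lists. It was 1.75 with the filter at the 60th percentile, which keeps only brighter genes. Besides Ascl2, Phlda2 and Igf2, these were Cdkn1c (2.86, signal 1170 to 8813), Peg10 (2.43), Sgce (2.00), Peg3 (1.75) and Slc22a18 (1.39). Slc22a18, with signals of 18.8 at day 0 and 140 at day 2, was at 0.95 with a constant of 112. The 2 kept probe sets of Igf2 gave 2.10 and 3.24.

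Other lineages gave smaller or mixed differences. Of 20 measured primitive endoderm genes 6 were at least 2-fold higher, including the basement membrane collagens Col4a2 (1.92) and Col4a1 (1.89), Plat (1.82), Serpinh1 (1.57) and the transcription factor Gata6 (1.46, signal 131 to 458). Apoe (−2.94), Lama1 (−1.66) and Amn (−1.51) were lower, and the median was 0.18 (95% interval −0.43 to 1.33; percentile 87.7), or 0.54 with the filter at the 60th percentile. The other gene of the 6 was Dab2 (1.33), at 0.59 when probe sets ending in _x_at, _s_at or _a_at were left out. None of 14 primitive streak and mesoderm genes was at least 2-fold higher, and Meox1 (−1.45) and Foxh1 (−1.07) were lower, Meox1 at −0.97 with a constant of 112. Their median was −0.29 (95% interval −0.63 to 0.23; percentile 1.28). Likewise 0 of 13 neuroectoderm and epiblast genes were higher, while Otx2 (−3.40, signal 1717 to 112) and Neurod1 (−1.32, and −0.86 with a constant of 112) were lower, with a median of −0.39 (95% interval −0.79 to 0.17; percentile 0.580) that was −0.05 without a filter on dim probe sets. Below the constant on average were 14 of the 28 mesoderm genes and 16 of the 29 neuroectoderm genes with a probe set.

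Hox genes, the regulators of body axis identity, were mostly near background, and 23 of the 33 with a probe set were below the constant. Hoxc8 (1.81, signal 9.40 to 173) and Hoxc9 (1.72, signal 35.0 to 243) were the 2 of the 10 measured ones that were at least 2-fold higher. The median of the 10 was 0.58 (95% interval 0.35 to 1.72; percentile 99.7), and 0.08 when dim probe sets were not filtered out. Among 39 other measured developmental transcription factors 10 were at least 2-fold higher and 1, Foxd3 (−2.68), at least 2-fold lower. Irx3 (2.67), Irx2 (1.32) and Gata6 were among the 10, and the other 7, including Gata3 (2.56), Msx2 (2.46) and Cdx2, are shared with the trophectoderm list. The median was 0.25 (95% interval −0.03 to 0.76; percentile 98.2), and 1.46 with the filter at the 60th percentile.

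Genes of the Polycomb complexes, which silence developmental genes through histone modification, moved in both directions. Of 18 measured components of Polycomb repressive complex 1, Pcgf5 (1.97, signal 1272 to 5144), Phc2 (1.44) and Yaf2 (1.30) were at least 2-fold higher and Phc1 (−2.59, signal 6400 to 1016) and Pcgf2 (−1.09, and −0.99 with a constant of 112) at least 2-fold lower. Phc1 is also in the pluripotency list, as are Jarid2 and Dnmt3l, which are given below. The catalytic members Ring1 (0.56) and Rnf2 (−0.40) stayed within 2-fold, and the median was 0.12 (95% interval −0.51 to 0.56; percentile 72.3), with a sign that turned under at least 1 alternative. In Polycomb repressive complex 2, Eed (−1.49, signal 10820 to 3812) and Jarid2 (−1.19) were lower and 0 of 12 higher, with Suz12 at −0.74, Epop at −0.74 and Ezh2, the methyltransferase, at −0.47. The median was −0.34 (95% interval −0.74 to 0.07; percentile 0.230). Of 8 DNA methylation genes, Tet1 (−1.90), Dnmt3l (−1.81) and Dnmt3a (−1.56) were lower and 0 higher, with Dnmt1 at 0.21 and Dnmt3b at 0.17, and the median was −0.71 (95% interval −1.90 to 0.21; percentile 0.0100). The mean over the probe sets of Dnmt3a was −0.80.

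**Figure D2:**
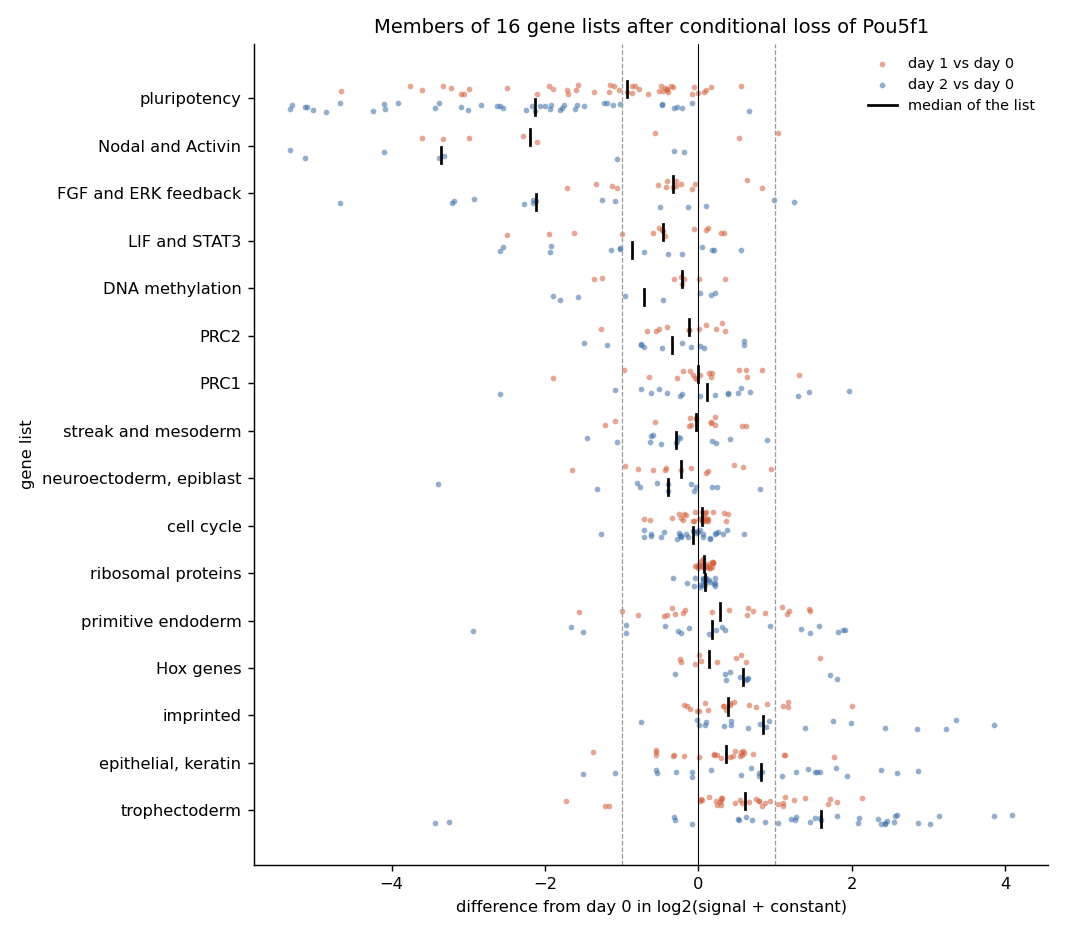
Difference from day 0 of each measured member of 16 gene lists, at day 1 (orange) and day 2 (blue), in log2(signal + constant). Each point is 1 gene, black bars are list medians and dashed lines mark 2-fold. The pluripotency median moved from −0.94 at day 1 to −2.13 at day 2, the trophectoderm median from 0.61 to 1.59, and the ribosomal protein medians of 0.07 and 0.09 stayed close to 0, with a sign that depends on the scaling.

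Signalling genes differed by pathway, but several of them are not separate from the results above. Lefty1, Lefty2, Tdgf1, Gdf3, Fgf4, Klf4, Klf5, Gbx2, Tfcp2l1 and Stat3 are also in the pluripotency list. Of 8 measured Nodal and Activin pathway genes 6 were at least 2-fold lower and 0 higher, with Gdf3 at −4.10, Lefty2 at −3.39 and Nodal at −3.32 beside Lefty1 and Tdgf1, and a median of −3.35 (95% interval −5.32 to −0.19), below all random lists. Without the filter on dim probe sets the median was −1.07. Of 15 genes of FGF signalling and its ERK feedback 10 were lower, including Etv5 (−3.21, signal 6975 to 701), Etv4 (−3.19, signal 582 to 14.0), the phosphatase gene Dusp6 (−2.93) and the Sprouty gene Spry4 (−2.28). The other kept probe set of Etv4 gave only −0.67 between day 1 and day 2. The receptor gene Fgfr1 was the 1 higher member, at 1.24, and at 0.60 when probe sets ending in _x_at, _s_at or _a_at were left out. The median was −2.11 (95% interval −2.93 to −0.13), below all random lists, and −1.25 as the mean over each gene's probe sets. Of 14 LIF and STAT3 targets 7 were lower and 0 higher, with the receptor gene Lifr at −2.59, Gbx2 at −2.54, Klf4 at −1.93 and Klf5 at −1.92, and a median of −0.86 (95% interval −1.93 to 0.18), below all random lists.

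BMP and Wnt targets were mixed, and Msx2, Dlx3, Gata2, Id2, Bmp4 and Ascl2 among them are also in the trophectoderm list. Of 13 BMP and SMAD genes, Msx2 (2.46), Dlx3 (2.08), Gata2 (1.60) and Id2 (1.46) were at least 2-fold higher and Bmp4 (−3.25) and Id1 (−1.04) lower, with a median of −0.19 (95% interval −0.34 to 1.60; percentile 5.93) that turned to 0.05 with the filter at the 60th percentile. Id2 was at 0.36 when probe sets ending in _x_at, _s_at or _a_at were left out. Of 9 Wnt targets, Ascl2 (3.86) and the Wnt inhibitor gene Dkk1 (2.96, signal 65.8 to 893) were higher, and Ccnd1 (−2.40), Notum (−1.95) and Lef1 (−1.07) were lower, Lef1 at −0.73 with a constant of 112. Their median was 0.41 (95% interval −1.95 to 2.96; percentile 94.98).

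Genes of cell division mostly stayed within 2-fold. Of 29 measured cell cycle genes 0 were at least 2-fold higher and 1, Mybl2 (−1.27), was lower, with Mcm3 at −0.71, Bub1 at −0.71 and Mcm6 at −0.62. The median was −0.07 (95% interval −0.25 to 0.07; percentile 11.8). Among 10 cyclin-dependent kinase inhibitors and D cyclins, Cdkn1c (2.86), Cdkn2c (1.28, and 0.94 with a constant of 112) and Cdkn1a (1.24) were higher and Ccnd1 (−2.40) was lower, with a median of 0.38 (95% interval −0.87 to 1.28; percentile 96.9). Of 18 p53 targets and apoptosis genes, Cdkn1a and Btg2 (1.21) were higher and Bcl2l11 (−1.05, and −0.99 as the mean over its probe sets) was lower, with Mdm2 at 0.78 and a median of 0.12 (95% interval −0.11 to 0.49; percentile 75.5) that turned to −0.01 with equal ribosomal protein medians. As a comparison, 0 of 21 ribosomal protein genes passed 2-fold, from Rpl37 at −0.32 to Rpl8 at 0.22, and their median of 0.09 (95% interval 0.02 to 0.14; percentile 79.6) was −0.04 after quantile normalisation. Of 12 reference genes 1 was higher, the class I light chain gene B2m (1.53, signal 509 to 1572). Their median was 0.20 (95% interval −0.21 to 0.39; percentile 92.2), with Gusb at 0.84, Polr2a at −0.81 and Ywhaz at 0.39.

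At day 1, when the Pou5f1 signal was already 40.8, the lower end again held pluripotency genes, and the higher end held Cdx2. After Pou5f1 (−4.67), the lowest genes were Slc7a3 (−4.14, signal 4361 to 195), Nr0b1 (−3.76), Lefty2 (−3.60, signal 1027 to 33.5), Enox1 (−3.51), Lefty1 (−3.33), Tcl1 (−3.22), Jam2 (−3.09), Trh (−3.06) and Tdgf1 (−2.99). The day 1 signals of Pou5f1, Lefty2 and Enox1 (2.80) lay below the constant, which limits their differences and leaves their place in the order unresolved. The highest were Parm1 (signal 589 to 3221, 5.08-fold), Cdx2 (2.14, signal 152 to 856), Tinagl1 (2.11), Igf2 (2.00, signal 2682 to 10890), S100a1 (1.96), the ATP-gated channel gene P2rx4 (1.94), Gadd45g (1.92), Mogat2 (1.88), Hip1 (1.83) and Cited1 (1.81). In total 305 genes were at least 2-fold higher and 330 at least 2-fold lower, where simulated unchanged arrays gave 48.1 and 54.2. The probe sets of some of these genes differed, and S100a1 (0.91) and P2rx4 (0.98) were under 2-fold without probe sets ending in _x_at, _s_at or _a_at, as was the mean over the probe sets of Hip1 (0.91). The other probe set of Igf2 gave 0.63. With equal array medians, which moved the median of all genes by −0.13, the split was 193 higher and 446 lower, and with equal ribosomal protein medians, which moved it by −0.15, it was 187 and 459.

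Among the lists, 21 of 43 pluripotency genes were at least 2-fold lower at day 1 and 0 higher, with a median of −0.94 (95% interval −1.60 to −0.49), while Nanog was at −0.09 and Sox2 at −0.49. Of the 8 Nodal and Activin genes 5 were lower and 1, Eomes (1.04), was higher, with Nodal at −2.29 and a median of −2.20 (95% interval −3.60 to 1.04). Both medians were below all random lists, and that of the Nodal and Activin genes was −0.56 without the filter on dim probe sets. In contrast, 4 of 15 FGF and ERK feedback genes were lower, with Fgf4 at −1.71, Etv5 at −1.34, Dusp6 at −0.05 and Spry4 at −0.23, and a median of −0.33 (95% interval −1.06 to −0.08; percentile 0.0800). Of the trophectoderm genes 10 were higher, including Cited1, Esx1 (1.72), Hand1 (1.69), Msx2 (1.39) and Gata3 (1.25), and 3 lower, and the median was 0.61 (95% interval 0.29 to 0.94), above all random lists. Plac1 (0.28), Ascl2 (0.66), Krt8 (0.48) and Krt18 (0.29) were still within 2-fold. With equal array medians Eomes (0.91), Fgfr2 (0.96), Peg10 (0.97) and Cldn4 (0.99), all of them among the 10, were under 2-fold. Gata3 was at 0.93 with a constant of 112 and Msx2 at 0.96 as the mean over its probe sets. Of the primitive endoderm genes 5 were higher, with Gata6 at 1.46, Col4a1 at 1.44 and Col4a2 at 1.18, and 1, Apoe (−1.55), was lower, with a median of 0.29 (95% interval −0.35 to 0.87). Dab2 (1.09) was 1 of the 5 and at 0.56 as the mean over its probe sets. In the Polycomb lists Phc1 (−1.89) and Eed (−1.27) were lower and Phc2 (1.32) was higher, and in the Hox list 1 gene, Hoxb9, was at 1.58 at day 1 and 0.65 at day 2. None of the 29 cell cycle genes and none of the 18 p53 targets passed 2-fold, with medians of 0.05 and 0.13, and the cell cycle median was −0.12 with equal ribosomal protein medians.

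Between day 1 and day 2 Plac1, Ascl2 and Phlda2 made most of their difference from day 0. Plac1 was higher at day 2 than at day 1 by 3.82 (signal 214 to 3740), Ascl2 by 3.20 (394 to 4081), Fgfbp1 by 3.06, Phlda2 by 3.02 (2979 to 24651) and Ldoc1 by 2.97. The lowest were Morc1 (−3.26), Fgf4 (−2.97), Dusp6 (−2.88, signal 1734 to 187), Etv4 (−2.77) and Stmn2 (−2.63). Another kept probe set gave less for some of these, with Fgf4 at −1.82, Stmn2 at −1.28 and Etv4 at −0.67. This step had 266 genes at least 2-fold higher and 337 lower, against 59.3 and 55.6 in simulated unchanged arrays. With equal array medians the balance turned round, to 312 higher and 281 lower. Of the FGF and ERK feedback genes 9 were lower in this step, with a median of −1.10 (95% interval −2.05 to 0.41). Of the 29 cell cycle genes 0 passed 2-fold in this step and 22 were below 0, with a median of −0.17 (95% interval −0.33 to −0.02; percentile 0.340).

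**Figure D3:**
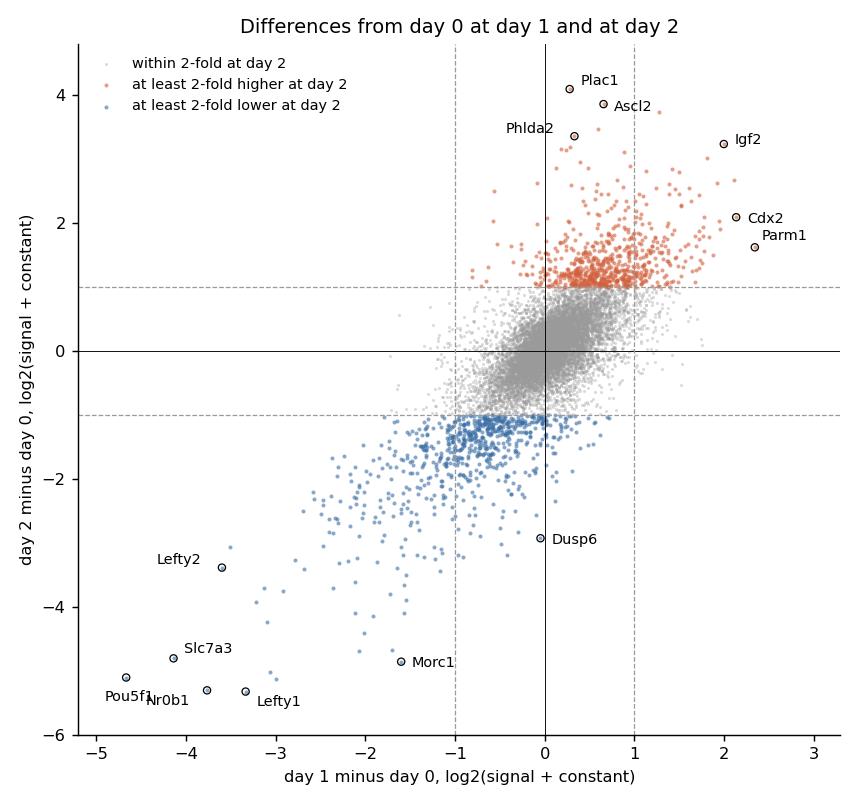
Difference from day 0 at day 1 (horizontal axis) and at day 2 (vertical axis) of 12717 genes, in log2(signal + constant). Orange points are the 668 genes at least 2-fold higher and blue points the 718 at least 2-fold lower at day 2, and dashed lines mark 2-fold. Pou5f1 is at −4.67 and −5.10, while Dusp6 is at −0.05 and −2.93 and Plac1 at 0.28 and 4.10.

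Of the 718 genes at least 2-fold lower at day 2, 258 (35.9%), among them Nr0b1, Lefty1 and Tdgf1, were already at least 2-fold lower at day 1. Of the 668 higher genes 164 (24.6%), among them Cdx2 and Cited1, were already higher. Independent lists of these sizes would share 18.6 lower and 16.02 higher genes. Simulated unchanged arrays had far shorter lists and are no like comparison for these overlaps. Of their 93.5 lower and 94.0 higher genes at day 2, 18.4 and 19.5 on average were already past 2-fold at day 1. The shared day 0 array alone can thus give a sizeable share. Both comparisons use the same day 0 array, so part of the excess may come from that shared array, and the difference between the directions was not tested. Under the alternatives of scaling, constant, filter and probe sets the 258 ranged from 200 to 364 and the 164 from 90 to 270.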

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

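No test in this part was chosen after its result was seen, and no explanation is weighed here. Some signal lay in probe sets that no comparison above uses, because the annotation names no single gene for them. Of 3939 such probe sets above the constant, 110 (2.79%) were at least 2-fold higher at day 2 than at day 0 and 140 (3.55%) at least 2-fold lower. Among probe sets with 1 gene name the shares were 4.77% and 5.09%. The highest of them was higher by 2.86 on the log2 scale, with signals of 966 at day 0, 3693 at day 1 and 7377 at day 2. The next was higher by 2.06, with signals of 184, 513 and 945. The lowest were at −5.27 (signals 4181, 601 and 54.2) and −4.85 (signals 1663, 126 and 3.70).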

How the results depend on the processing

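All tests in this part were planned. No paired analysis was possible because there was 1 array per day. Under the 11 alternatives of scaling, constant, filter and probe sets, 622 of 636 values of list medians stayed within their interval, or within the range of the members for the 2-cell stage list, which has no interval. The intervals cover the spread between members and are wide, so staying within one does not show that a median held. The Nodal and Activin median at day 2, for example, moved from −3.35 to −1.07 within its interval of −5.32 to −0.19. The log2 difference of Pou5f1 at day 2 was −5.80 with a constant of 27.9 and −4.30 with 112; at day 1 it was −5.14 and −4.04, and −5.42 with a floor in place of the constant. These follow from the alternatives themselves, since a smaller constant compresses dim signals less.

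Counts followed the size rule. At a 3-fold threshold 172 genes were higher and 300 lower at day 2 against day 0, 35 and 107 at day 1 against day 0, and 55 and 83 at day 2 against day 1. The 305 genes higher at day 1 became 193 with equal array medians, 187 with equal ribosomal protein medians, 469 with a constant of 27.9, 146 with 112, 530 with a floor and 202 with the filter at the 60th percentile, which tests fewer genes. For day 2 against day 1 the counts were 157 higher and 184 lower with a constant of 112, and 411 and 522 with a floor. Genes higher at both days numbered 108 with equal array medians, 103 with equal ribosomal protein medians, 270 with a constant of 27.9, 90 with 112 and 264 with a floor.

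The median of Hox genes at day 2 was 0.0775 without a filter, which adds dim genes, and that of other developmental transcription factors was 1.46 at day 2 and 0.81 at day 1 with the filter at the 60th percentile. The cell cycle median at day 1 was −0.0936 with equal array medians and −0.12 with equal ribosomal protein medians. Ribosomal protein medians lie too close to 0 for their sign to hold. At day 2 the median was 0.0167 with equal array medians, −0.0386 after quantile normalisation, −0.0591 with equal ribosomal protein medians, −0.00419 as a mean over probe sets and −0.0663 without probe sets ending in _x_at, _s_at or _a_at; at day 1 it was −0.0737, −0.0123 and −0.0979 under the 3 scalings and 0.00706 without those probe sets. The cause was tested no further than by these alternatives. In all, 15 list medians whose intervals include 0, the day 1 cell cycle median among them, changed sign under at least 1 alternative.

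Of 2908 values of 270 differences of named genes, 185 moved by more than the spread between probe sets and 1 changed sign. In 41 of these differences a gene past 2-fold ended under 2-fold under at least 1 alternative, among them Dab2, Fgfr1, Id2 and Mmp2. Unmatched random lists moved 4 of 58 list percentiles across the middle 95%. Dim signals limit the rest, and a difference between arrays below the constant was treated as not resolved. On the 3 arrays 41.4%, 38.5% and 40.05% of probe sets lay there. That these are near 40% follows from the definition of the constant as the 40th percentile, which is no measured limit of detection.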

Other observations

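The patterns below were noticed in these data, and no test was chosen after its result was seen. Of 15 measured genes of sterol synthesis 0 passed 2-fold at day 2, with Sc5d at 0.75, Hmgcs1, the first committed synthase, at 0.69 (signal 5858 to 9453), Msmo1 at 0.68 and Fdps at 0.59. The median was 0.45 (95% interval 0.17 to 0.59; percentile 99.7), or 0.32 with equal ribosomal protein medians, and at day 1 it was already 0.45 (95% interval 0.23 to 0.62), above all random lists. The day 1 median was as low as 0.29 under the alternatives. Glycolysis and hypoxia genes had a median of −0.02 (95% interval −0.20 to 0.39; percentile 34.0), with a sign that turned under 1 alternative, yet Pdk1 (−2.59, signal 6075 at day 0) and Pfkp (−1.95) were at least 2-fold lower and Ndrg1 (2.55, signal 501 to 3212) higher at day 2, with Hk2 at −0.71.

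Of 20 stress response genes, Jun (2.28, signal 363 to 1983), Gadd45b (1.63), Hmox1 (1.51), Hspa1b (1.20) and Hspa1a (1.08) were at least 2-fold higher at day 2 and Chac1 (−2.54), Gadd45a (−1.28) and Asns (−1.06) lower. Hspa1a was at 0.90 with a constant of 112. The median was 0.29 (95% interval −0.25 to 0.98; percentile 98.5). Of 14 germ cell genes Dppa3 (−1.78) and Prdm1 (−1.14, and −0.93 with a constant of 112) were lower and 0 higher, with Taf7l at 0.87, Stra8 at 0.83 and a median of 0.19 (95% interval −0.54 to 0.76; percentile 79.4). Of 5 measured genes of the 2-cell stage 0 passed 2-fold, with Zfp352 at 0.82, Usp17la at 0.81 and a median of 0.40 (percentile 93.3).

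Genes on the X chromosome were frequent among the higher genes. They made up 3.21% of the genes with a known chromosome, but 45 of 667 genes (6.75%) at least 2-fold higher at day 2 and 11 of 72 (15.3%) at least 4-fold higher, including Plac1, Nxf7, Ldoc1, Mbnl3, Nrk and Cited1, 6 of the 10 highest named genes. A gain of an X copy in most cells is argued against by the whole chromosome. Its median exceeded that of autosomal genes by 0.0749 (95% interval 0.01 to 0.15). A gain in a small part of the cells is not excluded. The X median of 0.12 was the highest of all chromosomes, followed by chromosome 13 at 0.09. Signal level is argued against too, since the percentage of X-linked genes was at percentile 100 of random sets of matched signal. Leaving out Rhox genes took the X-linked genes only from 45 of 667 to 43 of 665 (6.47%). Too few Rhox genes were measured as higher for that cluster to make up the excess. A candidate explanation is that X-linked genes of the trophoblast programme respond together. Without the trophectoderm list 39 of 643 genes (6.07%) were still X-linked. That list held few of the 45, and not Nrk or Ldoc1, so this cannot count against the explanation. No biological explanation was tested.

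FGF feedback genes had made little of their day 2 difference by day 1, less than Nodal pathway genes. The median share reached at day 1 was 60.5% for the 6 Nodal genes at least 2-fold lower at day 2, from 51.4% for Gdf3 upward, and 13.7% for the 10 FGF genes, from 1.56% for Dusp6 to 49.1% for Il17rd. Compression of dim signals by the constant is argued against, since with a constant of 27.9 the gap was 44.2 percentage points. The FGF share was also at percentile 0.06 of random lists drawn from all genes at least 2-fold lower, with a random median of 50.5%. Lower genes in general thus did not have so low a share. The pattern was noticed in these same values, so this percentile is no independent support for it. The Nodal share, at percentile 78.0 and with a random median of 49.2%, was ordinary for lower genes. Feedback genes may follow the loss of Fgf4, itself 1 of the 10 and lower by −1.71 at day 1, with a delay. This order was not tested and rests on 1 array per day.

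Some genes peaked at day 1. In 27 genes the day 1 signal was at least 2-fold above both other days, where simulated unchanged arrays gave 4.58. Among them were Smad6 (947, 2844 and 811), Nrp2 (445, 1377 and 289), Dmrt1 (1302, 3671 and 1548) and Hk1 (1711, 4310 and 2058). The simulation holds no shift of a whole array, and the day 1 array had the highest median signal, 92.5. Peaks were not recounted under other scalings. With equal array medians the peak genes Eomes (0.91) and Sox21 (0.95) were under 2-fold at day 1 against day 0. For the 11 peak genes with several probe sets, Nrp2 and Hk1 among them, probe set noise is argued against, since 15 of 16 other probe sets (93.8%) were also above both other days, against 29.3% over all genes, while 16 genes, Smad6 and Dmrt1 among them, have 1 probe set and were not checked. A trough at day 1 was seen in 26 genes, such as Myc (1165, 341 and 1745), Id3 and Lgals3, where simulated unchanged arrays gave 7.27. Most of these 26 had a day 1 signal below the constant, which limits their differences. Examples are Trem2 (86.2, 6.40 and 102) and Tns2 (84.7, 11.3 and 126), while Myc, Id3 and Lgals3 were brighter. The troughs stay open, since 4 of the 26 have several probe sets, with Myc, Id3 and Lgals3 not among them. For those 4, 2 of 8 other probe sets went the same way, close to the 24.8% over all genes. That share does not exclude probe set noise for those 4. A passing response to the loss of Oct3/4 and a peculiarity of the day 1 culture or array stay open for the peaks, since every probe set of a day shares its array.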
